A study of Mus musculus with 11 samples.

How the data were processed

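The material was placenta of CD1 mice, an outbred laboratory stock. Per the labels' protocols, pregnant dams received bisphenol A (BPA) in olive oil by gavage once a day from gestational day 1 to day 11, and placentas were collected on day 12. The dose was 0 (vehicle, the control group), 0.5 (low dose) or 50 (high dose) mg per kg body weight per day. Total RNA of 3 control, 4 low-dose and 4 high-dose samples was amplified and labelled with a 2-colour Agilent kit. Each sample was hybridised once in Cy3 and once in Cy5 on 11 whole-genome arrays. The labels call the samples biological replicates and do not say whether each was a single placenta, a litter or a pool. The p-values of single genes thus measure the spread between these samples as labelled. By the dyes in the labels, arrays 1 and 2 paired control 1 with low dose 1, arrays 3 and 4 paired control 2 with high dose 1, and arrays 5 to 11 joined the other 7 samples in a loop. These 3 sets of samples share no array with one another.

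The scanner files hold spot intensity on a linear scale, written by Agilent Feature Extraction 9.5.1.1, per the file headers. The mean signal and the median local background of each spot were used, neither of them normalized. A deposited table holds log2 ratios for the same arrays, which the authors made with limma, per the submitters' processing notes. Its limma version and its background and normalization methods are not given in the sources used here. To find its scale and direction, each of its columns was set against log2 of red (Cy5) over green (Cy3) background-subtracted signal, over spots with more than 200 intensity units in both channels. The correlation was 0.977 to 0.998 on arrays 5 to 11, and 0.643, 0.534, 0.909 and 0.535 on arrays 1, 2, 3 and 4, so the table holds red over green. The medians of its columns from array 1 to array 11 were -0.04, -0.04, -0.03, -0.03, 0.01, 0.02, 0.01, 0.04, 0.02, -0.03 and 0.02. How the authors centred it stays unknown. These values served as an alternative.

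Not every column of a scanner file came from the array it was filed under. In the files of arrays 1 to 4, the net signals equalled those of arrays 5 to 8 at 100% of spots (within 0.01 intensity units or 0.1%), while the mean signals were whole numbers from another scan. The red mean signals filed under arrays 6, 7, 9 and 10 matched the red net signals of arrays 9, 10, 6 and 7 at 100% of spots (within 1 intensity unit or 0.6% of the signal, after removal of the median offset). The red mean signal filed under array 11, labelled control 3, matched no array (at best 6.515% of spots). Mean signals were kept with the sample that the labels give for their file, and log2 ratios were formed within each file. The ratios filed under arrays 6, 7, 9 and 10 thus join green and red signals of different arrays. Effects of the array and the spot do not cancel in these ratios. For array 11 the array of the red signal is not known. The net signals served to trace columns, and the red net signal of array 11 also served in 1 check of that array's red channel. The headers name 2 slides, arrays 5 to 8 and arrays 9 to 11. By the traced signals, all high-dose channels of the loop lie on the first of these slides and all low-dose channels on the other, except low dose 4 in Cy5. The slide behind the mean signals of arrays 1 to 4 is not known.

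The spot flags and processed signals of most files belong to the net signals and not to the mean signals. The scanner's detection and outlier flags were therefore not used. A probe counted as detected in a channel where its mean signal less background exceeded the 95th percentile of the 153 negative control spots, and in a sample where both channels did. Probes detected in at least 3 of the 11 samples were kept. Signals were background-corrected with normexp (offset 50) and normalized within each file by loess, with the 1486 control spots at weight 0. Spots of the same probe were averaged. The level of each sample came from a least-squares fit to the log2 ratios of its files with 1 dye term per probe. The files hold 43379 probe spots for 41174 distinct probes. Gene names were taken from the table of the GRCm38.p6 assembly for 22944 probes by accession, 6664 by symbol and 3095 by an older symbol, and 8471 probes kept the name in the files. Coordinates are those of the probes in the files (build mm7). An annotation of that build was not used here, so exons and untranslated regions are not stated. The filter kept 32761 probes of 22361 genes, 17607 of them with a symbol in that table. Of 7318 genes with more than 1 probe, the probe with the highest mean log2 intensity was tested. Probes of the same gene moved in opposite directions, both at an unadjusted p under 0.05, for 9 genes in low dose against control, 0 in high dose against control and 6 in high against low dose.

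Genes were tested with limma 3.58.1 on all 11 samples, with the group and the hybridisation set as terms (6 residual degrees of freedom, 1.817 prior degrees of freedom) and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Groups were taken from the label of the channel that held the RNA. The 3 comparisons were each dose against control and high against low dose. Gene lists for 11 cell types and 17 pathways or gene families, 28 in all, each with at least 5 measured genes, were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry. Camera asks whether the genes of a list differ from all other genes. At the preset correlation its p-values do not measure how a list mean varies between samples. Fry asks whether the genes of a list move, on balance, one way. The design, the lists, 29 of the 33 alternative settings and the rule for named genes were fixed before the data were examined. That rule takes, for each dose against control, the 10 highest and 10 lowest log2 fold changes among genes that pass, filled up to 20 by smallest unadjusted p where fewer pass. For high against low dose it takes 10 in the same way. It adds from each list the 3 members of smallest unadjusted p in the dose comparison with the smaller list p. Genes without a symbol of their own were counted but not named (3, 4 and 3 in the 3 comparisons), and 114 distinct genes were named.

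The steps were tested on simulated data with 200 changed genes among 22361. For low dose against control, 52.9%, 84.8% and 90.9% of genes changed by 1, 2 and 3 on the log2 scale were recovered, and 5 unchanged genes were called. For high dose against control, the shares were 54.5%, 91.2% and 93.8%, with 3 unchanged genes called. The cell cycle list, lowered by 0.5 in the high-dose group, was recovered in high dose against control (limma camera, adjusted p = 5.81e-36). In that run 0 other lists were called. The shift was larger than the means later found for that list (-0.11 against control and -0.12 against the low dose). Noise was drawn independently for each gene, so the run cannot show how often lists of correlated genes are called by chance. Alternatives covered the background correction, normalization, the deposited ratios, the detection filter, the choice of probe, the treatment of channels and arrays, the loop alone, the replicate number or the slide as a block, array weights, eBayes with trend and robust, and each sample left out in turn. The other 4 settings were chosen after the data were seen. They left out array 11, left out array 11 with control 3 and high dose 3, fitted a dye term per scan, or paired channels by the array they were traced to. Computations used R 4.3.3, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.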

Results

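Placental transcripts were measured in 11 samples of CD1 mice, of which 3 came from vehicle-treated dams, 4 from dams given 0.5 mg BPA per kg per day and 4 from dams given 50 mg per kg per day. BPA is a plastics monomer that binds estrogen receptors. The 11 2-colour arrays gave 22 channels, and 22361 genes passed the detection filter. The median spot signal less local background ranged from 40.3 to 337 intensity units over the channels. The share of probe spots above the negative controls was 59.0 to 94.8% in arrays 5 to 11 and 66.7 to 78.7% in the green channels of arrays 1 to 4, but 38.4 to 53.3% in the red channels of arrays 1 to 4. Of the genes named here, Zgrf1, Mrgprg, Cyp4f13, Igfbp4, Tbx21, C1qb, Aif1, Slc2a2, Mttp, Cxcl15, Thbs2, Nr1i2, Greb1, Sult1a1, Tnfrsf10b, Phka2, Ogn, Tap1, Zfy1, Ddx3y and Eif2s3y were above background in both channels of only 1 of 3 control samples, so their fold changes against control rest partly on signals near the background of a channel. Fgfr1, Ascl2, Stmn3, Eif4ebp2, Myo10, Cpsf4l, Vav3, Itga4, Ccl5, Adgre1, Epb42, Rbp4, Esrrb, Zrsr1, Egln1 and Anln were so in 2 of 3. At the high dose Anln, Ogn and Eif2s3y were so in 2 of 4 samples and Ddx3y in 1, and at the low dose Eif2s3y in 2 of 4. Itga4, Tbx21, Ccl5, Epb42, Cxcl15, Esrrb, Slc1a2, Ogn, Zfy1 and Ddx3y were so in 3 of 4 low-dose samples, and Zgrf1, Stmn3, Itga4, Igfbp4, Tbx21, Adgre1, Epb42, Slc2a2, Nr1i2, Greb1, Sult1a1, Slc1a2 and Zfy1 in 3 of 4 high-dose samples. The Cy5 channels of control 1 and control 2 had the highest detection thresholds of all channels (369.4 and 377.4 intensity units). Only 40.7 and 38.4% of their probe spots lay above these. A gene not above background in these controls may thus reflect those red channels and not a low level in controls. The number of arrays limits the precision. The median standard error of a log2 fold change was 0.16 for each dose against control and 0.14 for high against low dose.

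The red and green channels of a sample were compared across genes, as deviations from the mean of all channels of that dye. In the loop, where the samples lie on different arrays, Pearson's r between the channels of the same sample was 0.22 to 0.685 for 6 samples and -0.22 for control 3. The Cy5 channel of control 3 correlated at 0.87 with the Cy3 channel of high dose 4 and at 0.63 with its Cy5 channel. Some channels that the traced signals place on the same array also correlated more with each other than with their own sample in the other dye: low dose 2 in Cy5 with low dose 4 in Cy3 at 0.674 (own 0.22), low dose 2 in Cy3 with low dose 3 in Cy5 at 0.546, and control 3 in Cy3 with high dose 2 in Cy5 at 0.666. In the dye-swapped pairs, the log2 ratios of arrays 1 and 2 correlated at 0.073 and those of arrays 3 and 4 at -0.011. A difference between samples that repeats in a swap gives a negative value. These ratios still hold the dye term of each probe, which pushes the correlation up, so they do not show whether the swaps repeated a difference. Genes are not independent replicates, so these values carry no p-value.

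**Figure D1:**
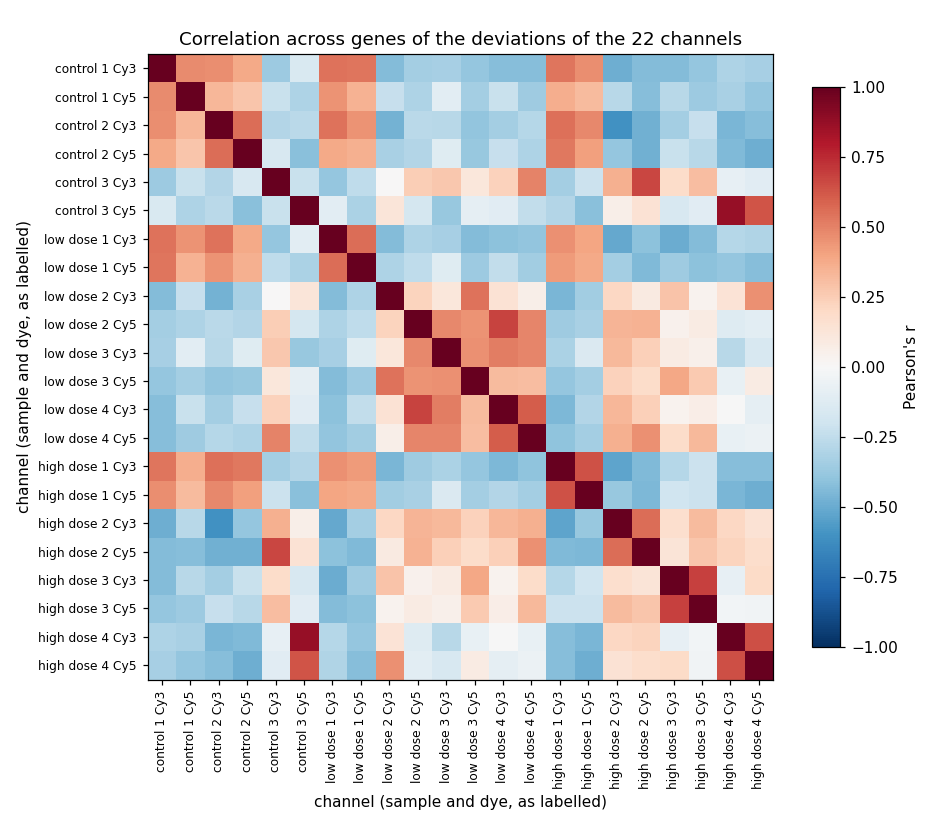
Pearson's r across genes (colour scale, from -1 to 1) between the deviations of the 22 channels, each named on both axes by sample and dye as labelled. The Cy5 channel of control 3 stands at -0.22 with the Cy3 channel of the same sample and at 0.87 with the Cy3 channel of high dose 4.

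The first comparison asks which placental transcripts differ between the low dose and vehicle. No gene passed, and the genes with the smallest unadjusted p lay mostly above control (16 of 20 named genes higher, 4 lower). Mthfd2, a mitochondrial enzyme of folate metabolism (NM_008638, mm7 chromosome 6, 83331895 to 83331954), had a log2 fold change of 0.67 ± 0.12 (SE, 4 low-dose against 3 control samples). Pold1, the catalytic subunit of DNA polymerase delta (NM_011131, chromosome 7, 40707773 to 40707903), stood at 0.55 ± 0.11. Fgfr1, a fibroblast growth factor receptor (NM_010206, chromosome 8, 24330065 to 24330124), stood at 0.54 ± 0.12, and Ascl2, an imprinted transcription factor required for the spongiotrophoblast (NM_008554, chromosome 7, 139395814 to 139395873), at 0.40 ± 0.09. Lsr, the lipolysis-stimulated lipoprotein receptor, stood at -0.48 ± 0.10. Fbxo15, an F-box protein of pluripotent cells, stood at -0.52 ± 0.11 and Atp5e, a subunit of ATP synthase, at -0.53 ± 0.12. Zgrf1 stood at 1.27 ± 0.26, above background in 1 of 3 control and 4 of 4 low-dose samples. Myadm, Klk4, Mapkap1, Mrgprg, Tmc5, Wdr48, Tmem192, Eif4ebp2, Gak, Ppp1r13b and Myo10 lay between 0.31 and 0.73. These are values of 1 probe per gene, and only 2 of 4 Fgfr1 probes, 1 of 3 Myadm probes and 1 of 2 Ppp1r13b probes had that sign. Stmn3, a stathmin family member, was not above background in any low-dose sample. In plain channel means its control level was 1.38-fold higher (measured in 2 of 3 control samples). Its high-dose level was 1.09-fold higher (measured in 3 of 4 samples). These means leave out the set term. The fitted log2 fold changes were -0.42 ± 0.10 in low dose against control and 0.12 ± 0.09 in high against low dose.

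Limma called 0 of 22361 genes in low dose against control (smallest adjusted p = 0.742). At an unadjusted p under 0.05 there were 1331 genes, 831 higher and 500 lower, where chance gives 1118. Other limma settings called 0 genes except array weights with 4474 and channels paired by the array they were traced to with 2167. Of the 28 lists, camera called 0, with 2 at an unadjusted p under 0.05. Endothelial genes had a mean log2 fold change of 0.16 (17 of 24 genes higher, limma camera, adjusted p = 0.0914 and 0.968 with an estimated correlation), with Icam2, an adhesion molecule of endothelium, at 0.49 ± 0.21, Cldn5, a tight-junction protein, at 0.42 ± 0.18 and Mmrn2 at 0.53 ± 0.29. Genes of glycogen metabolism had a mean of 0.15 (19 of 24 higher, limma camera, adjusted p = 0.0914 and 0.858 with an estimated correlation). Fry called 0 lists, with 2 at an unadjusted p under 0.05. Adjusted over the list alone, 0 lists held a gene that passed. With median centring in place of loess, camera called 15 lists. Endothelial cells also passed without low dose 3 (0.19, limma camera, adjusted p = 0.0289) and without background correction (0.11, 0.0444), and glycogen metabolism without the filter on dim probes (0.15, 0.0469). Spongiotrophoblast and glycogen cells passed without background correction (0.24, 0.0444), with the deposited ratios (0.30, 0.0330) and without array 11, control 3 and high dose 3 (0.42, 0.0232).

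The high dose was compared with vehicle to find which transcripts differ at 50 mg per kg per day. No single gene passed. By limma camera 4 gene lists did at the preset correlation, and none of them with an estimated correlation (adjusted p = 0.434 for each). Markers of spongiotrophoblast and glycogen cells, the endocrine cells of the junctional zone, rose by a mean of 0.26 on the log2 scale (24 of 33 genes higher), a mean that turned to -0.0298 with array weights. Genes of glycogen metabolism rose by 0.14 (18 of 24 higher), a mean that was 0.0654 without background correction, 0.0682 with the deposited ratios and 0.0716 with channel means without the set, none of which passed. Cell cycle genes fell by 0.11 (42 of 52 lower) and nutrient transporters fell by 0.10 (32 of 48 lower), and both means turned positive when median centring replaced loess (0.15 and 0.12, or 0.04 and 0.01 relative to the median of all genes). Among the spongiotrophoblast and glycogen cell genes, Prl3c1, a prolactin family hormone (NM_013766, mm7 chromosome 13, 26569146 to 26569205), stood at 0.72 ± 0.19 (SE, 4 against 3 samples) and Ascl2 at 0.31 ± 0.09, while Phlda2, an imprinted inhibitor of placental growth, stood at -0.61 ± 0.19. Other lists hold 4 of these genes (Prl3c1, Prl7d1, Ascl2 and Phlda2). Of the glycogen genes, Phka2, a subunit of phosphorylase kinase, stood at 0.32 ± 0.14, Ppp1r3c, which targets phosphatase to glycogen, at 0.48 ± 0.23 and Pygl, a glycogen phosphorylase, at 0.34 ± 0.21, signs shared by 1 of 3 Phka2 probes and 1 of 2 Pygl probes. In the cell cycle list, Pcna, the sliding clamp of DNA replication (NM_011045, chromosome 2, 131990537 to 131990674), stood at -0.47 ± 0.12, Prc1, a protein of the division spindle, at -0.29 ± 0.12 and Anln, needed for cytokinesis, at -0.42 ± 0.18. Of the transporters, the glutamate carriers Slc1a1 and Slc1a2 stood at -0.44 ± 0.10 and -0.32 ± 0.13 (3 of 4 Slc1a2 probes with that sign), and Atp1b1, a subunit of the sodium pump, at -0.38 ± 0.14.

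The 20 genes of smallest unadjusted p at the high dose, none of which passed, were 11 higher and 9 lower. Arhgef3, a Rho exchange factor, stood at -0.48 ± 0.09 and Ran, the GTPase of nuclear transport, at -0.46 ± 0.10. Flvcr2, a membrane transporter, stood at -0.70 ± 0.14, Slco4a1, an organic anion transporter, at -0.63 ± 0.17, Fbxo15 at -0.46 ± 0.11 and Ehd4 at -0.37 ± 0.10. Pdgfrb, the platelet-derived growth factor receptor of pericytes, had the lowest value, -0.84 ± 0.24. Mdfi, an inhibitor of myogenic transcription factors, stood at 0.55 ± 0.14, Lrp1, a lipoprotein receptor, at 0.64 ± 0.18, Fgfr1 at 0.42 ± 0.12 and Phb, a mitochondrial prohibitin, at 0.38 ± 0.11. Cpsf4l, Cyp4f13, Acoxl, Vav3 and Fosl2 lay between 0.31 and 0.58. Only 2 of 4 Fgfr1 probes and 1 of 2 Cpsf4l probes had that sign.

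Limma called 0 of 22361 genes in high dose against control (smallest adjusted p = 1.00), with 380 at an unadjusted p under 0.05, 186 higher and 194 lower, where chance gives 1118. All 33 other limma settings also called 0 genes. By limma camera the adjusted p was 0.00608 for spongiotrophoblast and glycogen cells, 0.0290 for glycogen metabolism, 0.000312 for the cell cycle and 0.0368 for nutrient transporters. Fry called 0 lists, with 1 at an unadjusted p under 0.05. Adjusted over the list alone, 0 genes passed in any list. In levels after removal of the fitted set term, all 4 high-dose samples lay above the control mean for spongiotrophoblast and glycogen cells and for glycogen metabolism. For the cell cycle 3 of 4 lay below it, and 4 of 4 for nutrient transporters. That term makes high dose 1 mirror control 2, so high dose 1 is not an independent count. It also makes low dose 1 mirror control 1. For spongiotrophoblast and glycogen cells, high dose 2 (-0.103) barely cleared the control mean (-0.109), and 2 of 4 lay above every control sample. Yolk sac endoderm genes, markers of a neighbouring tissue, reached 2.35 in high dose 3 and -0.34 to 0.34 in the other 10 samples, as relative log2 levels after removal of the fitted set term. With the slide as a block over channels, the limma camera adjusted p was 2.87e-06 for spongiotrophoblast and glycogen cells, 9.6e-06 for the cell cycle, 0.00866 for nutrient transporters and 0.0596 for glycogen metabolism. That fit holds 21 channels of the 11 samples with the sample as a random block (correlation 0.0464, 15 residual degrees of freedom), so the channels of a sample count almost as separate replicates and these p-values are too small. On shared arrays, high dose 1 less control 2 and high dose 2 less control 3 were 0.37 and -0.10 for spongiotrophoblast and glycogen cells, 0.21 and 0.14 for glycogen metabolism, -0.21 and -0.08 for the cell cycle, and -0.13 and -0.04 for nutrient transporters.

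These list calls were lost when single samples were left out, some of them with means about as large. Spongiotrophoblast and glycogen cells lost the call without control 1 or low dose 1, which share a set (limma camera, adjusted p = 0.238, mean 0.23), and without high dose 3 (0.101), where the mean dropped to 0.13. Glycogen metabolism lost it without control 2 or high dose 1 (0.134, mean 0.10), control 3 (0.303, mean 0.15) or high dose 3 (0.101, mean 0.12), and the cell cycle without control 2 or high dose 1 (0.0526, mean -0.07) or control 3 (0.130, mean -0.09). Nutrient transporters kept it in 2 of 11 such fits, without high dose 3 and without low dose 2, and reached 0.306 without high dose 1 or control 2. The others gave 0.238 without control 1 or low dose 1, 0.130 without control 3, 0.202 without high dose 2, 0.0820 without high dose 4, 0.0656 without low dose 3 and 0.0587 without low dose 4, with means of -0.11 to -0.08 in these fits. Without array 11, whose red channel is the doubtful one of control 3, the adjusted p of the 4 lists was 0.340, 0.259, 0.187 and 0.240. The median of all genes was then 0.0926, and relative to it the means were 0.18, 0.20, -0.09 and -0.06, against 0.26, 0.13, -0.12 and -0.10 relative to the median with that array.

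**Figure D2:**
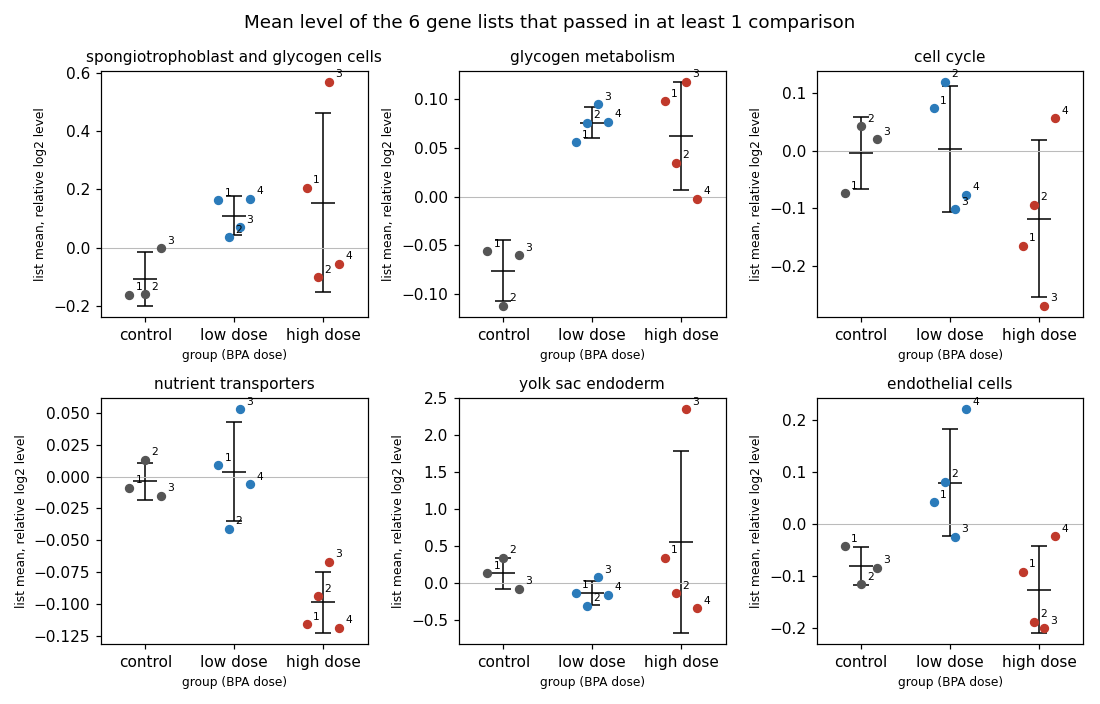
Mean level of the 6 lists that passed in at least 1 comparison (vertical axes, relative log2 level after removal of the fitted set term), by group on the horizontal axes, with numbered points for samples and lines for the group mean ± SD (3 control, 4 low-dose and 4 high-dose samples). High dose 3 stands at 2.35 for yolk sac endoderm, the 4 high-dose samples lie at -0.12 to -0.07 for nutrient transporters against -0.02 to 0.01 in controls, and the differences from control for cell cycle and nutrient transporter genes turn positive with median centring. The set term ties low dose 1 to control 1 and high dose 1 to control 2, so the points and SDs are not all independent. The control and low-dose means mirror each other.

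The doses were then compared with each other to find transcripts that differ between them. No gene passed. By limma camera 3 lists did at the preset correlation, and none of them with an estimated correlation (adjusted p = 0.473 for endothelial cells and the cell cycle, 0.808 for yolk sac endoderm). Endothelial genes fell by 0.21 on the log2 scale at the high dose relative to the low dose (20 of 24 lower), cell cycle genes fell by 0.12 (33 of 52 lower) and yolk sac endoderm genes rose by a mean of 0.69 (21 of 26 higher). The yolk sac mean came from high dose 3, which stood at 2.35 while the other high-dose samples stood at -0.34 to 0.34, and it was -0.04 without that sample. Pcna had a log2 fold change of -0.74 ± 0.11 (SE, 4 against 4 samples), Prc1 of -0.53 ± 0.11 and Mcm3, a subunit of the replicative helicase, of -0.34 ± 0.09. Among the endothelial genes, Icam2 stood at -0.48 ± 0.20 and Cldn5 at -0.32 ± 0.17. Rbp4, the retinol carrier made by yolk sac endoderm, stood at 2.21 ± 0.79 with high dose 3 included. Of the 10 genes of smallest unadjusted p, none of which passed, 5 were higher and 5 lower. Ndufa2, a subunit of respiratory complex I, stood at 0.75 ± 0.10, Phb at 0.69 ± 0.10, Psme1, a proteasome activator, at 0.69 ± 0.11, Agpat4 at 0.50 ± 0.08 and Mrtfa, a coactivator of serum response factor, at 1.06 ± 0.16. Snx5, a sorting nexin, stood at -0.87 ± 0.12, Ube2k, a ubiquitin-conjugating enzyme, at -0.91 ± 0.14, Gak at -0.73 ± 0.11 and Slco4a1 at -0.97 ± 0.15. Only 3 of 4 Ube2k probes, 1 of 2 Gak probes and 1 of 2 Mrtfa probes had that sign.

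Limma called 0 of 22361 genes in high against low dose (smallest adjusted p = 0.473), with 1160 at an unadjusted p under 0.05, 318 higher and 842 lower, where chance gives 1118. Other limma settings called 674 genes over the 22 channels, 382 over 11 ratios taken as independent, 1 with the slide as a block, 8991 with array weights and 8075 with channels paired by the array they were traced to. By limma camera the adjusted p was 0.00155 for endothelial cells, 5.98e-05 for the cell cycle and 0.00867 for yolk sac endoderm. All 3 calls were lost with channels paired by the array they were traced to (0.122, 0.122 and 0.493, means -0.14, -0.01 and 0.47) and with array weights (0.0905, 0.126 and 0.919, means -0.26, -0.03 and -0.00967). Fry called 0 lists, with 4 at an unadjusted p under 0.05. Adjusted over the list alone, 12 cell cycle genes passed, and 1 gene passed in each of the lists for spongiotrophoblast and glycogen cells, xenobiotic metabolism, nutrient transporters and immediate early genes. In the levels after removal of the set term, all 4 high-dose samples lay below the low-dose mean for endothelial cells and 3 of 4 for the cell cycle. For yolk sac endoderm 2 of 4 lay above it. There too, high dose 1 is tied to control 2, and low dose 1, which enters the low-dose mean, is tied to control 1. With the slide as a block over channels, the limma camera adjusted p was 0.0240 for endothelial cells, 1.72e-07 for the cell cycle and 0.198 for yolk sac endoderm, whose mean fell to 0.39, again with the 21 channels counted almost as separate replicates. On the array that held high dose 4 and low dose 4 together, the difference was -0.30 for endothelial cells, 0.10 for the cell cycle and -0.27 for yolk sac endoderm. Without high dose 3 the adjusted p rose to 0.0634 for endothelial cells (mean -0.18), 0.0563 for the cell cycle (mean -0.06) and 0.642 for yolk sac endoderm (mean -0.04). Without low dose 2, nutrient transporters passed (-0.12, limma camera, adjusted p = 0.0450). The yolk sac call was also lost without low dose 2 (0.241) and without control 1 or low dose 1 (0.0523).

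The other cell-type lists did not pass in any of the 3 comparisons as fitted here, though several did in other settings. The sign of 45 of the 84 list means turned when median centring replaced loess, and of 44 when each mean was taken relative to the median of all genes. In high dose against control, decidual stroma had a mean log2 fold change of 0.18 (16 of 22 genes higher). High dose 3 stood at -0.938 and the other high-dose samples at 0.387, 0.730 and 0.747, and without high dose 3 the list passed against control (0.55, limma camera, adjusted p = 0.000225) and against the low dose (0.75, 0.0108). It also passed against control with 6 further settings, among them array weights (0.45, 0.000506) and the 22 channels (0.28, 0.0157). Of its genes, Alpl, the alkaline phosphatase of decidua, stood at -0.66 ± 0.37 and Igfbp4 at 0.25 ± 0.16. Macrophage and neutrophil genes stood at 0.13 (14 of 19 higher; 0.27 with the slide as a block, limma camera, adjusted p = 0.0156), with C1qb at 0.24 ± 0.17, Aif1 at 0.28 ± 0.23 and Adgre1 at -0.40 ± 0.27. Labyrinth trophoblast, the exchange tissue of the placenta, stood at -0.08 (18 of 25 lower; -0.15 without background correction, limma camera, adjusted p = 0.0426), with the gap junction gene Gjb2 at -0.65 ± 0.35, Itga4 at -0.42 ± 0.25 and Cdx2 at 0.42 ± 0.41. Fetal erythroid genes stood at -0.10, but passed without control 2 or high dose 1 (-0.26, limma camera, adjusted p = 0.000726), in the loop alone (-0.32, 0.00570), with the replicate block added (-0.37, 0.00137) and with array weights (-0.25, 1.89e-05). Their member Epb42 stood at -0.73 ± 0.37, Alas2, the first enzyme of heme synthesis in red cells, at -0.48 ± 0.25 and Epor at 0.45 ± 0.25. Trophoblast giant cells stood at -0.04, uterine natural killer and T cells at -0.02 (0.22 without high dose 3, limma camera, adjusted p = 0.0296, but -0.40 with the replicate block added, 0.0241), smooth muscle and myometrium at -0.07 and uterine glands and epithelium at -0.01. Among their members, Plat stood at -0.53 ± 0.23, Serpinb9e at 0.27 ± 0.17, Gzma at 0.49 ± 0.46, Tbx21 at -0.14 ± 0.14, Ccl5 at -0.26 ± 0.28, Sorbs1 at -0.35 ± 0.19, Acta2 at -0.25 ± 0.18, Lmod1 at -0.20 ± 0.16, Elf3 at 0.00 ± 0.11 and Foxa2 at 0.12 ± 0.26. Ctsq, a cathepsin of sinusoidal giant cells, stood at -0.79 ± 0.29 in low dose against control. Cxcl15 was not above background in any high-dose sample. In plain channel means without the set term, its low-dose level was at least 1.005-fold higher (measured in 3 of 4 samples). Slc2a2 and Mttp of the yolk sac list stood at 0.20 ± 0.14 and 0.22 ± 0.17 in high dose against control. Low-dose means against control ran from -0.26 for yolk sac endoderm and -0.21 for fetal erythroid cells to 0.22 for spongiotrophoblast and glycogen cells (limma camera, adjusted p = 0.549 for each). With median centring, camera called spongiotrophoblast and glycogen cells (0.95 relative to the median of all genes, limma camera, adjusted p = 0.00113), giant cells (0.85, 0.0248), endothelial cells (0.76, 0.00611) and labyrinth trophoblast (0.63, 0.0188) in low dose against control. Relative to that median it turned the sign of the means of giant cells, smooth muscle and glands at both doses, decidual stroma, macrophages and fetal erythroid cells at the low dose, and labyrinth trophoblast, endothelial cells and uterine natural killer and T cells at the high dose. For Itga4, Slc2a2 and Acta2, 4 of 5, 1 of 2 and 3 of 4 probes had the sign given.

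Lists chosen for known targets of BPA, for steroid hormones, imprinting, angiogenesis and matrix did not pass as fitted here. With the slide as a block, estrogen-responsive genes passed in high against low dose (-0.11, limma camera, adjusted p = 0.0240). Nuclear receptors had a mean log2 fold change of -0.05 at the low and 0.006 at the high dose against control, and estrogen-responsive genes of -0.09 and -0.06. Esrrb, an orphan receptor of trophoblast stem cells, stood at -0.42 ± 0.14, Ncor1, a corepressor, at 0.63 ± 0.22 and Nr1i2, the pregnane X receptor, at 0.26 ± 0.09 at the low dose. Greb1, an estrogen receptor target, stood at 0.23 ± 0.12 and 0.22 ± 0.12 at the low and high dose, and Aqp8, a water channel, at -0.57 ± 0.27 at the high dose. Steroid hormone genes stood at 0.09 and 0.02, with Hsd17b7 at 1.16 ± 0.53 and Cyp17a1 at 0.22 ± 0.10 at the low dose. Xenobiotic metabolism stood at -0.02 and 0.003, with Sult1a1, a phenol sulfotransferase, at 0.36 ± 0.15 and 0.40 ± 0.15. Imprinted genes stood at 0.03 and -0.01, with Zrsr1 at 0.28 ± 0.09 and Nap1l4 at -0.29 ± 0.10 at the low dose. Angiogenesis genes stood at 0.06 and 0.01, with Thbs2, an inhibitor of angiogenesis, at 0.78 ± 0.24 and 0.66 ± 0.24 and Ednra, an endothelin receptor, at 0.70 ± 0.26 at the low dose. Extracellular matrix stood at -0.09 and 0.06, with Ogn at -0.31 ± 0.12 and Nid1 at 0.39 ± 0.22 at the low dose. With median centring in place of loess, which moved the median of all genes to 0.33, camera called angiogenesis (0.47 relative to that median, limma camera, adjusted p = 0.0270), steroid hormone (0.62, 0.0218) and imprinted genes (0.53, 0.0188) in low dose against control. Relative to the median of all genes, it turned the sign of extracellular matrix at the low dose, imprinted genes at the high dose and nuclear receptors, xenobiotic metabolism and estrogen-responsive genes at both. For Esrrb, Ncor1 and Nap1l4 at the low dose, 1 of 2, 3 of 6 and 1 of 3 probes had the sign given.

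Stress and signalling lists also did not pass as fitted here. In high dose against control, the unfolded protein response passed without background correction (0.12, limma camera, adjusted p = 0.0426) and with the slide as a block (0.15, 0.0422), the antioxidant response with the slide as a block (-0.09, 0.0187), and interferon and inflammation with the replicate block added (-0.27, 0.000806). At the high dose against control, the unfolded protein response stood at 0.11 and the hypoxia response at 0.09, both at an unadjusted p under 0.05 (limma camera, adjusted p = 0.194 for each and 0.434 with an estimated correlation), as was yolk sac endoderm at 0.42 (limma camera, adjusted p = 0.166 and 0.951 with an estimated correlation). Yolk sac endoderm passed without control 2 or high dose 1 (0.64, 0.0427), high dose 2 (0.64, 0.0266) or high dose 4 (0.70, 0.00100). Without high dose 3 it passed with the opposite sign (-0.14, 0.0474). With high dose 3 included, it also passed with the deposited ratios (0.88, 0.000452) and without background correction (0.69, 0.00288). The replicate block gave 1.24 (1.79e-06) when added and 0.80 (0.000657) in place of the set. Channel means gave 0.74 (0.00475) without the set and 0.57 (0.0200) with it. Ppp1r15a, a phosphatase subunit of the stress response, stood at 0.21 ± 0.10, Sel1l at 0.15 ± 0.09, Herpud1 at 0.37 ± 0.24, Egln1, an oxygen sensor, at 0.21 ± 0.11, P4ha1 at 0.37 ± 0.19 and Slc2a3, a glucose transporter, at 0.24 ± 0.11. The antioxidant response stood at -0.05, apoptosis and p53 targets at -0.005, interferon and inflammation at -0.02, immediate early genes at -0.05 and the 5 measured Y-linked genes at -0.07. Mt1 stood at 0.42 ± 0.26, Prdx6 at -0.30 ± 0.21, Sesn1 at -0.48 ± 0.40, Zfy1 at -0.07 ± 0.14, Ddx3y at -0.29 ± 1.1 and Eif2s3y at -0.005 ± 1.91. At the low dose, Btg2, a growth inhibitor induced by p53, stood at 0.59 ± 0.22, Tnfrsf10b at -0.19 ± 0.08, Bbc3 at -0.24 ± 0.10, Tap1 at 0.48 ± 0.17, Stat2 at 0.51 ± 0.23, Irf9 at -0.40 ± 0.18 and Hspa1a, a heat shock protein, at -0.51 ± 0.21. Low-dose means against control were 0.03 for the unfolded protein response, 0.02 for hypoxia, -0.01 for the antioxidant response, -0.08 for apoptosis, -0.07 for interferon, -0.06 for immediate early genes and -0.45 for Y-linked genes. With median centring, camera called the unfolded protein response (0.87 relative to the median of all genes, limma camera, adjusted p = 0.00110) and hypoxia (0.71, 0.00215) at the low dose, and both at the high dose (0.33, 0.00108 and 0.26, 0.00296). At the low dose it also called the antioxidant response, apoptosis and immediate early genes, with means of the opposite sign (0.84, 0.42 and 0.63). Relative to that median, the antioxidant, apoptosis, interferon and immediate early lists turned sign at both doses. For Prdx6 and Zfy1 at the high dose, 3 of 4 and 1 of 2 probes had the sign given, and for Tnfrsf10b and Irf9 at the low dose, 1 of 3 and 1 of 2. Mean and median differed in sign for 6, 5 and 4 lists in the 3 comparisons in order, and the camera direction and the mean for 5, 3 and 4. In low dose against control, both held for decidual stroma, uterine natural killer and T cells, estrogen-responsive and xenobiotic genes, mean and median alone for giant cells and the antioxidant response, and camera and mean alone for immediate early genes. In high dose against control, mean and median differed for uterine natural killer and T cells, glands, angiogenesis, imprinted genes and apoptosis, and camera and mean for glands, nuclear receptors and xenobiotic genes. In high against low dose, both held for giant cells, estrogen-responsive and immediate early genes, mean and median alone for uterine natural killer and T cells, and camera and mean alone for xenobiotic genes.

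**Figure D3:**
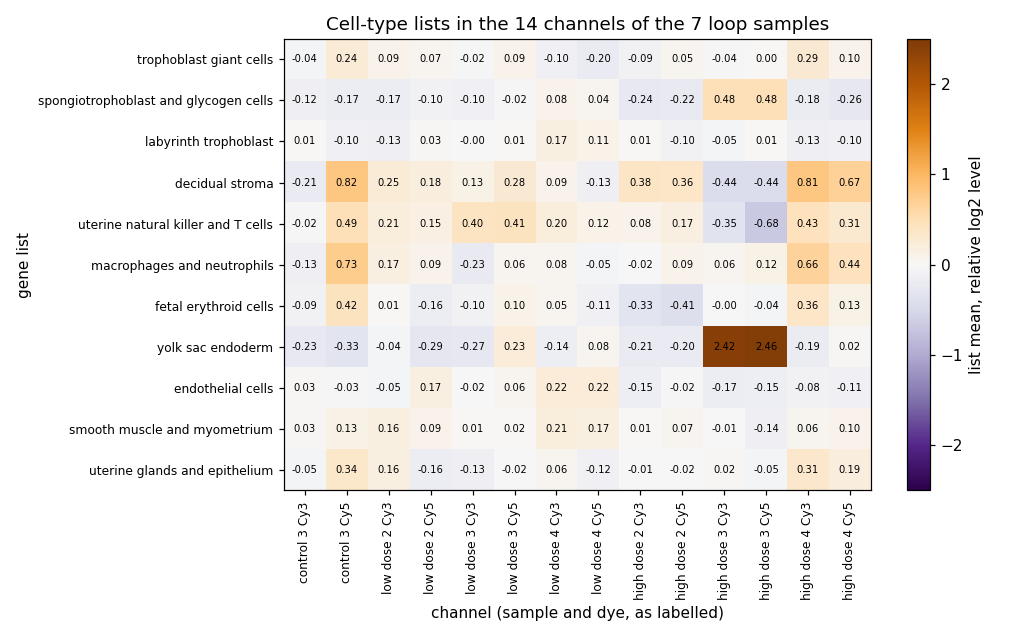
Mean level of the 11 cell-type lists (vertical axis; colour and printed value, log2 relative to the mean of all channels of that dye) in the channels of the 7 loop samples (horizontal axis, sample and dye as labelled). Both channels of high dose 3 stand at 2.42 and 2.46 for yolk sac endoderm, and the channels of control 3 stand apart for decidual stroma, at -0.21 in Cy3 and 0.82 in Cy5.

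Both doses were set against the same 3 control samples, so their fold changes share chance values. Across 22361 genes the fold changes of low and high dose against control correlated at 0.288 and had the same sign for 66.8% of genes. All 11 samples, simulated without any change in the same design, gave a correlation of 0.580 (0.544 to 0.611 over 100 simulations). The sign was the same for 69.7% of genes. The covariance was 0.0142 against 0.0434 in the simulations. The observed values lay below the simulated ones. Noise was drawn independently for each gene there, which makes the simulated range narrower than correlated genes would give. The simulations thus do not show whether the observed values differ from those of shared controls with no effect. The controls could not be split, since a part would hold fewer than 2 samples. The correlation was 0.871 without array 11 and -0.248 without high dose 3, and 0.569 without control 1 or low dose 1. Fgfr1, Ascl2 and Fbxo15 were named for both doses, with the same sign in each.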

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

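Every test of the Cy5 channel of control 3 except that of the array's own red signal, the tests of yolk sac tissue and of the high dose, and those of that channel's part in the cell cycle result and of high dose 3 in its part against control were chosen after the result was seen. How the slide test, the test of the array's own red signal and those of the cell cycle without an array or a sample are read was also settled after their values were seen, while the splits of the samples were fixed earlier.

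In 14 of 284 groups of 4 samples, 1 sample lay far from the other 3, its gap to the nearest sample, as a share of the group's range, exceeding Dixon's 95% critical value. Chance gives about 1 in 20 such groups, here 14.2. The sample apart was high dose 3 in 6 groups, high dose 2, high dose 4 and low dose 3 in 2 each, and high dose 1 and low dose 4 in 1 each. In high dose 3 the ratio of gap to range was 0.868 for the mean of the antioxidant list (level -0.10 against -0.03 in the other 3 samples), 0.865 for Pold1 (-0.02 against -0.10), 0.907 for Alpl (-1.56 against -0.44), 0.832 for Gzma (-0.83 against 0.70), 0.881 for Lmod1 (-0.47 against 0) and 0.861 for Zfy1 (-0.22 against 0.13). In high dose 2 it was 0.917 for Ascl2 (0.02 against 0.13) and 0.865 for Flvcr2 (-0.72 against -0.57). In high dose 4 it was 0.906 for Ehd4 (-0.16 against -0.37) and 0.864 for Ppp1r15a (0.24 against 0.06). In high dose 1 it was 0.95 for Slc1a2 (-0.47 against -0.20). Within the low-dose group it was 0.957 for Cyp4f13 (low dose 3, 0.53 against 0.24), 0.864 for Snx5 (low dose 3, 0.36 against 0.19) and 0.845 for Atp1b1 (low dose 4, 0.32 against 0.11).

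The Cy5 channel labelled control 3 departed from the Cy3 channel of that sample. Another RNA in the channel is a candidate explanation, since its lower correlation with the channels of high dose 4 was 0.63 against -0.22 with its own partner, although channels of different samples on the same array reached 0.674. A dye effect was not decided: the mean correlation with other Cy5 channels less that with Cy3 channels was -0.089, but the deviations are centred by dye, which holds this value down. A dim channel was excluded with 87.4% of its probe spots above the negative controls. The red net signal in that array's file correlated at 0.147 with control 3 in Cy3. It correlated most with low dose 3 in Cy3, its partner on the array (0.459). Channels of different samples traced to the same array correlated at anything from -0.078 to 0.674. Sharing an array can thus raise a correlation, and whether that red signal holds control 3 cannot be told by this test.

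Yolk sac endoderm genes were high in high dose 3. Tissue of the yolk sac in that sample is a hypothesis that its test left undecided. Of 26 measured genes, 76.9% were higher there than in each of the other 6 loop samples, between the bounds of 80% and 50%. The genes that were not stood, relative to the mean of those 6 samples, at 0.045 for Hnf1b, 0.113 for Gata4 and -0.013 for Slc2a2. Mttp stood at 0.361, Ctsz at -0.237 and Sox17 at -0.82. Hnf1b, Gata4 and Slc2a2 hardly varied over the loop samples, with relative levels of -0.101 to 0.069, -0.139 to 0.109 and -0.051 to 0.083. The share fell below the upper bound in part through these flat genes, which say little on the tissue. Ctsz and Sox17 varied more and went against it. The most abundant products of that tissue stood, relative to the mean of those 6 samples, at 4.58 for Afp, 5.51 for Apoa1, 4.45 for Trf and 1.05 for Ttr on the log2 scale, and 1 gene of the list, Foxa2, is also held by another list. A single array or dye was excluded, because the lower channel of high dose 3 lay 2.18 above the highest other channel. In the test of the high dose, the mean of the other 3 high-dose samples lay at -0.39 relative to the highest low-dose or control sample. A mean set against a single highest value falls below it easily, so this test decides little. Without high dose 3 the list mean was -0.14 against control and -0.04 against the low dose. The rise was thus not shared by the other high-dose samples, but an effect of the dose in high dose 3 alone is not excluded.

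Cell cycle genes were lower at the high dose. The slide cannot be told apart from the dose: on the array that held high dose 4 and low dose 4 the difference was 0.097, which met the prediction written for a slide effect but lies below its standard error over genes (0.0996), while with the slide as a block the limma camera adjusted p in high against low dose was 1.72e-07, in a fit that counts 21 channels of 11 samples almost as separate replicates. The Cy5 channel of control 3 stays open for the part against control: without that array the limma camera adjusted p was 0.187, but the mean relative to the median of all genes went only from -0.12 (SD over genes 0.144) to -0.09 (SD 0.395), so the call ended with a wider spread and most of the difference left. In the part against the low dose the list still passed without that array (limma camera, adjusted p = 0.00744). The relative mean there went from -0.13 (SD 0.338) to -0.15 (SD 0.284), so that difference did not rest on the channel. The makeup of high dose 3 also stays open for the part against the low dose. Without that sample the limma camera adjusted p was 0.0563 and the relative mean -0.07 (SD 0.522). In the part against control the list still passed without high dose 3 (limma camera, adjusted p = 0.00368), while the relative mean went from -0.12 to -0.08. Part of that difference was thus left without this sample. Camera p-values at the preset correlation do not measure how a list mean varies between samples, so that call does not exclude its makeup as a cause.

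The samples of each comparison were also divided in all 35 ways into groups of the same sizes. The splits did not follow the hybridisation sets, which stayed a term of the fit. In some splits of a dose against control, both samples of a pair, such as control 1 and low dose 1, fell in the same group. That pair then says nothing on the comparison, so shares of splits are not exact rates of chance. In low dose against control, 35 splits gave at least the 0 genes found (at most 1 in another split), 9 gave at least 1331 at an unadjusted p under 0.05 (at most 5075) and 35 at least the 0 lists (at most 4). In high dose against control, 35 gave at least 0 genes (at most 57), 23 at least 380 at an unadjusted p (at most 6162) and 18 at least 4 lists (at most 11). In high against low dose, 35 gave at least 0 genes (at most 5678), 8 at least 1160 at an unadjusted p (at most 8978) and 24 at least 3 lists (at most 10). Where the count found is 0, every split reaches it by construction, so those splits decide nothing. Chance is not excluded for the other 5 counts. The split of high dose 1, high dose 2, high dose 4 and low dose 2 from the other 4 samples called 5678 genes, and that of high dose 1, high dose 3, low dose 3 and low dose 4 called 5379, which points to a structure of the samples. Both splits set high dose 2, high dose 4 and low dose 2 against high dose 3, low dose 3 and low dose 4. After removal of the set term, Y-linked genes stood at 0.626, 0.804 and 0.75 in the former and at -1.027, -1.126 and -0.903 in the latter. Decidual stroma stood at 0.73, 0.747 and 0.429 against -0.938, -0.323 and -0.306. Not every list divided these samples so. These splits were picked after the counts were seen, and what separates the samples was not tested.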

How the results depend on the processing

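All 33 other settings and both other list tests were compared with the reported values, and 4 of the settings were chosen after the result was seen. No named gene passed in any setting except 30 of 342 gene values over the 22 channels, 23 with 11 ratios as independent, 130 with array weights and 87 with channels paired by the traced array. None of these reversed, and uncalled values changed sign in at most 76 cases, with median centring. Over the 33 settings, the adjusted p by limma camera passed in 26 for spongiotrophoblast and glycogen cells (2.87e-06 to 0.790), 16 for glycogen metabolism (0.00367 to 0.613), 26 for the cell cycle (8.27e-08 to 0.787) and 12 for nutrient transporters (0.000506 to 0.991) in high dose against control. In high against low dose it passed in 23 for yolk sac endoderm (2.33e-06 to 0.951), 29 for endothelial cells (3.94e-05 to 0.293) and 29 for the cell cycle (1.68e-07 to 0.203). These counts hold repeated outcomes. A dye term per scan changed no call, with the same median fold changes as reported. Leaving out control 1 or low dose 1 gave the same result, as did leaving out control 2 or high dose 1. The alternative with the scanner's processed signals was not run, because those columns belong to other arrays in most files. Red signals of arrays 1 to 4 stood above the negative controls at 38.4 to 53.3% of spots, which limits what the pairs of control 1 with low dose 1 and control 2 with high dose 1 can show.

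Genes called in low dose against control numbered 4474 with array weights (2618 higher, 1856 lower) and 2167 with channels paired by the traced array. In high against low dose they numbered 674 over 22 channels, 382 with 11 ratios as independent, 1 with the slide as a block, 8991 with array weights and 8075 with traced arrays, and the cause was not tested. The fits over channels count the channels of a sample as nearly separate replicates (sample correlation -0.143 for the 22 channels and 0.0464 with the slide as a block). Array weights ran from 0.314 (high dose 3) to 10.5 (high dose 2). With the replicate block added to the set or in its place limma called 0 genes in each comparison. With that replicate block added the lists called were 0, 5 and 3. It kept the call of spongiotrophoblast and glycogen cells in high dose against control, lost those of glycogen metabolism (0.0866), the cell cycle (0.139) and nutrient transporters (0.985), and gained 4 other lists. In place of the set it called 0, 3 and 3, with the losses of glycogen metabolism (0.252) and nutrient transporters (0.215). Same-numbered samples of different groups correlated at -0.361 to 0.659, over 0.1 in 6 of 10 pairs, and 5 of 11 samples correlated best with their own number, so the numbers do not give a pairing.

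Lists called in low dose against control numbered 2 without background correction, 15 with median centring, 1 with the deposited ratios, 1 without the filter, 2 with the slide as a block and 1 without array 11, control 3 and high dose 3. In high dose against control they numbered 7 without background correction, 1 with every probe, 2 with the mean of probes, 2 with the loop alone, 7 with the slide as a block, 0 without array 11 and 2 without array 11, control 3 and high dose 3. They numbered 0 with an estimated correlation and 0 with fry. In high against low dose they numbered 15 with median centring, 1 with genes detected in all 11 samples, 0 with array weights, 0 with traced arrays, 1 without array 11, control 3 and high dose 3, 0 with an estimated correlation and 0 with fry. Leaving out 1 sample gave 0 to 1, 1 to 5 and 1 to 3 lists in the 3 comparisons. The cause was not tested.

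Median centring moved the median of all genes from 0, 0.01 and 0.01 to 0.33, 0.11 and -0.20 in the 3 comparisons, and leaving out array 11 moved it to 0.16, 0.09 and -0.05. Leaving out array 11, control 3 and high dose 3 moved it to -0.10 in high against low dose. Values that reversed with median centring were, in low dose against control, giant cells 1.18, antioxidant response 1.17, apoptosis 0.75 and immediate early genes 0.96. In high dose against control they were cell cycle 0.15 and nutrient transporters 0.12, or 0.04 and 0.01 relative to that median. In high against low dose they were giant cells -0.87, spongiotrophoblast and glycogen cells -0.72, unfolded protein response -0.77, hypoxia -0.67, apoptosis -0.54 and immediate early genes -0.75. Relative to the median of all genes, immediate early genes did not turn there (-0.003 as reported and -0.55 with median centring). With the slide as a block, decidual stroma 0.37 and macrophages 0.29 (low dose against control) and estrogen-responsive genes -0.11 (high against low dose) reversed. With array weights, spongiotrophoblast and glycogen cells -0.0298 (high dose against control) and yolk sac endoderm -0.00967 (high against low dose) did. Leaving out 1 sample gave, in high dose against control, -0.148 to 0.225 for uterine natural killer and T cells and -0.14 to 0.702 for yolk sac endoderm, and -0.0442 to 1.048 for yolk sac endoderm in high against low dose, where the values without high dose 3 (0.225, -0.14 and -0.0442) reversed. Without array 11, cell cycle 0.00446 and nutrient transporters 0.0338 took the opposite sign in high dose against control, but stayed at -0.09 and -0.06 relative to the median of all genes. Without array 11, control 3 and high dose 3 yolk sac endoderm -0.46 reversed in high against low dose. The cause was not tested.

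The correlation of the fold changes at both doses, 0.288 as reported, was 0.0593 without background correction, 0.732 with median centring, 0.665 with channel means without the set, 0.716 with the loop alone, 0.754 with the replicate block added, 0.631 with it in place of the set and 0.871 without array 11. It reversed to -0.110 with array weights, -0.460 with traced arrays and -0.237 without array 11, control 3 and high dose 3. Leaving out 1 sample gave -0.248 to 0.569. The cause was not tested.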

Other observations

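The values here were chosen after the results were seen. Lists for cell types and for Y-linked genes differed between samples in both dyes, as log2 deviations from the mean of all channels of that dye (Cy3 then Cy5). These deviations still hold the offset between hybridisation sets. Values of control 1, control 2, low dose 1 and high dose 1 thus cannot be set against those of the loop. After removal of the set term, decidual stroma stood at 0.387 in high dose 1 and -0.108 in control 2. Y-linked genes stood at 0.995 and 0.741 in high dose 4, 0.645 and 0.562 in low dose 2, 0.553 and 0.201 in low dose 1, 0.398 and -0.347 in high dose 2, and -0.131 and 1.292 in control 3. Their levels after removal of the set term were -1.027 in high dose 3, -1.126 in low dose 3 and -0.903 in low dose 4. Decidual stroma, the maternal side of the placenta, stood at 0.815 and 0.673 in high dose 4, -0.831 and -1.074 in control 2, -0.399 and -0.516 in high dose 1 and -0.436 and -0.440 in high dose 3. Uterine natural killer and T cell genes stood at 0.430 and 0.309 in high dose 4, -0.351 and -0.677 in high dose 3 and 0.398 and 0.413 in low dose 3. Macrophage and neutrophil genes stood at 0.658 and 0.444 in high dose 4 and -0.324 and -0.623 in control 2.

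Spongiotrophoblast and glycogen cell genes stood at 0.482 and 0.503 in high dose 1, 0.476 and 0.484 in high dose 3, -0.236 and -0.223 in high dose 2, -0.181 and -0.256 in high dose 4 and -0.331 and -0.363 in control 1. Endothelial genes stood at 0.221 and 0.217 in low dose 4. Fetal erythroid genes stood at -0.328 and -0.405 in high dose 2. Extracellular matrix genes stood at 0.190 and 0.266 in high dose 3. They stood at -0.334 and -0.498 in high dose 1, whose level after removal of the set term was 0.021.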
